A study of Drosophila melanogaster with 4 samples.

How the data were processed

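RNA sequencing was done on total RNA from dissected intestines of female flies, in 2 samples of a kdm5 mutant (alleles k6801 and 10424) and 2 samples of the strain w1118, each of 30 intestines, per the labels' protocols. Flies were kept at 25 degrees C, 50% humidity and a cycle of 12 hours of light and 12 hours of dark, and only RNA with an integrity number above 8 was used, per the labels' protocols. The labels call the 2 samples of a genotype separate samples and do not say whether the flies came from separate crosses or days, so p-values measure the spread between these samples, which may be in part technical.

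The single deposited table gave transcript identifiers, a p-value and the TPM of each of the 4 libraries, per the file headers. The file headers name the values TPM, which is by definition an estimate of transcript abundance as a share of 1000000 transcripts in each library. That total was assumed and could not be checked, because only selected transcripts are listed. Shares of total TPM, TPM outside the list and the scaling to it rest on this assumption. The submitters' processing notes name Cufflinks and DESeq, with no role or version. The aligner, genome build, annotation and strand setting are not given in the sources used here. Whether the authors' deposited p-values were adjusted for multiple tests is not stated. The smallest was 2.42e-06 and the median 0.013, and no 2 transcripts with different TPM had an equal p, which adjustment often produces. The number of transcripts the authors tested is also not stated. As all p lay below 0.05, the table was treated as a list selected on the comparison, and nothing was inferred about transcripts outside it. The authors' p-values, adjusted here as if all 35694 annotated transcripts had been tested, gave 0 transcripts at adjusted p < 0.05 (smallest 0.0864). All 1761 p-values as deposited lay under 0.05.

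Transcript identifiers were matched to the Ensembl release 115 annotation of BDGP6.54, which may not be the authors' annotation. Of 1761 transcripts 1741 matched, to 1526 genes; the other 20 kept their identifier. Positions are 1-based and from that annotation. Of the listed transcripts, 52 shared all 4 TPM values with another listed transcript. TPM keeps no depth, so no counting interval was given, and precision is described by the SD of 2 libraries or the SE of the fit.

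The test was written for counts if the file held them and for normalised values otherwise. The file held TPM, so limma 3.58.1 with a mean-dependent prior variance (limma-trend) was run in R 4.3.3 on log2(TPM + 1), mutant against w1118, with all 4 libraries and no replicate block. Fold changes on that scale understate the change of low transcripts. Adjusted p-values are Benjamini-Hochberg, over the 1761 listed transcripts in the planned test. A fold without the word log2 is the ratio of group mean TPM, given only where both means were at least 0.5 TPM; apart from DptA and gammaTry, folds that moved by over 1.5 times when 1 library was left out were replaced by group means after the data were examined. limma's prior variance was itself estimated from selected transcripts. The annotation-wide adjusted p counts every annotated transcript outside transposable elements as a test, whether or not the authors tested it, and was added after the data were examined.

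Gene lists (33) were fixed before the data were examined, and 8 of their members matched no symbol. They were tested with camera at a preset inter-gene correlation of 0.01, over the other listed transcripts, with Benjamini-Hochberg adjustment over the 13 lists with at least 5 listed genes. Direction was tested with an exact binomial test, and chromosome arms with Fisher's exact test of higher against lower calls. The named transcripts followed a rule fixed before the data were examined: Kdm5; among called transcripts with a mean of at least 5 TPM and both mutant values on the same side of both w1118 values, the 12 highest and 12 lowest by log2 change; in each list up to 4 called members with the smallest adjusted p, or the listed member with the smallest p if none was called; w and ry; and the 5 called transcripts with the highest mean level. The rule gave 103 transcripts of 99 genes, of which 78 transcripts passed the annotation-wide test.

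The steps were tested on simulated data. Without selection, 71% of log2 changes of 2 and 19% of log2 changes of 1 were recovered among 1761 simulated transcripts, and 5.26% of the calls were false. In 35000 simulated transcripts with no change, 2025 passed the limma threshold of 0.05. Refitted alone, 1999 of these (98.7%) were called, and 0 were called when all simulated tests were counted. Selection and calls used the same limma p, which nearly fixed the 98.7%. The deposited list was selected on the authors' p, so neither result is an estimate for it. camera recovered the shifted list among 20 simulated lists and called 0 others. These transcripts were simulated independently and without selection. The simulation therefore does not test false list calls where members vary together or were selected for change.

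Alternatives planned before the data were examined were a replicate block, leaving out each library and a pseudocount of 0.1. Minimum means of 1 and 5 TPM, an adjusted p below 0.01 and an absolute log2 change of at least 1 were also planned. So were leaving out transcripts at 0 in any library, camera with an estimated correlation, fry, leaving out arm 2L, and leaving out members of several lists. Added later were a crossed block, scaling each library to its TPM outside the listed transcripts, counting identical transcripts once, the annotation-wide adjustment and Fisher's test of direction for lists. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 were used for summaries.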

Results

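RNA was measured in dissected intestines of female fruit flies (*Drosophila melanogaster*) aged 3 to 5 days. The groups were a kdm5 mutant carrying the alleles k6801 and 10424 (2 samples) and w1118, a white-eyed laboratory strain used as the wild type (2 samples). Kdm5, also called lid, encodes a histone demethylase that removes methyl groups from lysine 4 of histone H3. Each sample pooled 30 intestines. The labels name the source as the whole animal in one field and the tissue as intestine in another; the protocol describes dissected intestines. The question set by the study's design was which genes differ in expression between the genotypes in the intestine.

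The values were in TPM, a measure of transcript abundance scaled to the same total in each library, of 1761 transcripts from 1526 matched genes, and every transcript carried a p below 0.05 in the authors' deposited table. The table is therefore a list selected on the comparison itself. With each library's total TPM taken as 1000000, the listed transcripts held 15.6% and 15.3% of it in the mutant libraries. In the w1118 libraries they held 23.9% and 23.5%. TPM keeps no record of sequencing depth, so the depth of each library is unknown. The smallest log2 ratio of mean TPM was 0.82 among transcripts listed as higher in the mutant, and the one nearest to 0 among those listed as lower was -0.58.

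**Figure D1:**
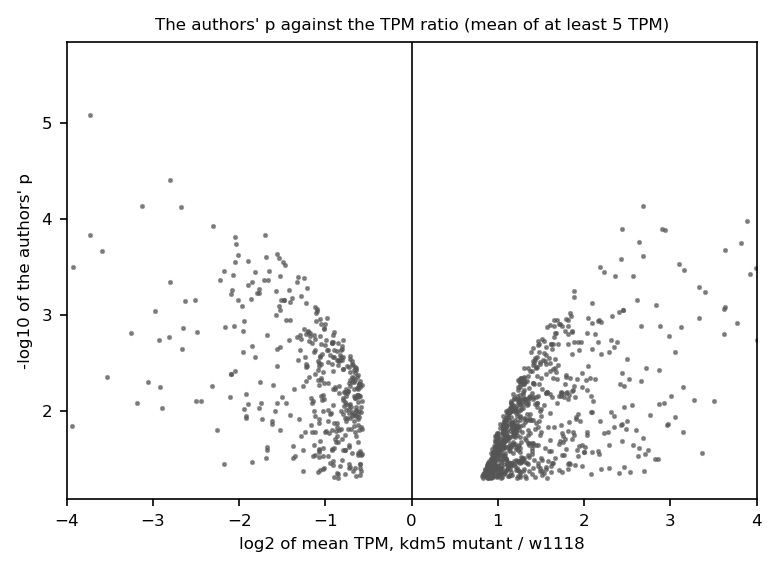
Each point is a listed transcript with a mean of at least 5 TPM and a log2 ratio within the axis limits; the horizontal axis is the log2 ratio of mean TPM, kdm5 mutant over w1118, and the vertical axis is -log10 of the p in the authors' deposited table. Points end at 0.82 on the right, where p lies near its limit, and at -0.58 on the left, where p spans a wider range.

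The mutated gene was measured first. Of the Kdm5 transcripts, 1 was listed (FBtr0307071, chromosome arm 2L, 5989463 to 5999501, minus strand, in the BDGP6.54 annotation). It stood at 0.0768 and 0.0361 TPM in the mutant libraries and at 1.43 and 0.639 TPM in the w1118 libraries, so each library lay on the side its label gives. The log2 change was -0.92 ± 0.26 (SE, n = 2 per group), with limma adjusted p = 0.0054 over the listed transcripts and 0.11 with every annotated transcript counted as a test. With a pseudocount of 0.1 in place of 1, which understates low transcripts less, the log2 change was -2.78 (adjusted p = 0.00069 over the listed transcripts). Without mutant replicate 1 or mutant replicate 2 the adjusted p over the listed transcripts was 0.064 or 0.077. Where the 2 alleles lie in relation to this transcript is not given in the sources used here. The marker genes w and ry, which common fly transgenes carry, were both higher in the mutant. The w transcript rose from 0.0065 ± 0.00919 to 11.1 ± 3.23 TPM (SD, n = 2), and w1118 carries a mutated w. The ry transcript, which encodes xanthine dehydrogenase, rose from 8.46 ± 0.792 to 29.9 ± 2.32 TPM (SD, n = 2).

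In the mutant intestine, all 12 listed transcripts of antimicrobial peptides rose, as did 9 of 10 of the Toll pathway and Bomanins and 20 of 23 of glutathione S-transferases and UDP-glycosyltransferases. All 5 listed lysozyme transcripts fell, and of 19 listed Jonah and trypsin transcripts 11 fell and 3 rose. None of the 13 gene lists tested stood apart from the other listed transcripts by camera with an estimated correlation (smallest adjusted p = 0.29). The lysozymes had too few listed genes to be tested. With 2 libraries per group the correlation is estimated from few degrees of freedom, so this result does not settle whether a list stands apart. DptA, which encodes the antibacterial peptide Diptericin A, rose from 3.89 ± 2.79 TPM in w1118 to 473 ± 320 TPM in the mutant (SD, n = 2), a 122-fold difference of means that ran from 63.5- to 247-fold when 1 library was left out. The lipase Lip3 rose from 0.26 ± 0.0416 to 45.3 ± 5.21 TPM, and the alpha-amylase relative Amyrel rose from 3.53 ± 2.47 to 126 ± 54.5 TPM. The trypsin gammaTry fell from 1203 ± 589 to 37.5 ± 44.3 TPM (17.5- to 193-fold when 1 library was left out), and the abundant protease Jon99Fi fell 12.1-fold, from 11260 ± 649 to 932 ± 95.5 TPM.

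Of the 1761 listed transcripts, 1036 were higher and 725 lower in the mutant. On log2(TPM + 1), limma called 1358 at adjusted p < 0.05 over the listed transcripts, of which 946 were higher and 412 lower (69.7% higher). The exact two-sided binomial p against equal numbers was 1.2e-48, a description because transcripts are not replicates. It cannot test the lean, because the list was selected unevenly and 58.8% of it was already higher. Listed transcripts began at a log2 ratio of mean TPM of 0.82 if higher and -0.58 if lower. The share of higher calls was therefore in part set by the list. In simulated libraries with no change, 98.7% of the transcripts first selected by limma at the threshold of 0.05 were then called by limma. Selection on the same p nearly fixed this outcome. The deposited list was selected on the authors' p, and 1443 of its 1761 transcripts had unadjusted limma p < 0.05. The share of 98.7% is therefore not an estimate for the deposited list. Adjustment over the listed transcripts does not limit false calls in a list already selected for small p. With all 35694 annotated transcripts outside transposable elements counted as tests, a setting chosen after seeing the data, limma called 540 transcripts of 490 genes, 387 higher and 153 lower. In this text, rose and fell are used only of transcripts in this smaller set, and a p called annotation-wide is adjusted in that way. Apart from DptA and gammaTry, a fold is given only where no single library, left out, moved it by over 1.5 times; other changes are given as group means. The smaller count was 0 without mutant replicate 1 and 0 without mutant replicate 2, where limma had 1293 and 1217 transcripts at unadjusted p < 0.05, and it was 282 without w1118 replicate 1. The p-values in the authors' deposited table, all 1761 under 0.05, gave 0 transcripts when adjusted in the same way (smallest adjusted value 0.0864). The limma count over the listed transcripts was 758 without mutant replicate 2, and 580 and 721 without w1118 replicates 1 and 2.

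Among the highest transcripts by the rule fixed beforehand, p24-2, which encodes a protein of the p24 cargo receptor family, stood at 118 ± 69.4 TPM in the mutant and 0.0904 ± 0.0224 TPM in w1118 (SD, n = 2). The CG1304 transcript rose 49.7-fold, IM18 rose from 3.74 ± 2.82 to 125 ± 60 TPM, and CG34040 from 4.45 ± 5.18 to 105 ± 2.42 TPM. Among the lowest, a Gdh transcript (FBtr0089497), one of several encoding glutamate dehydrogenase, fell from 75.8 ± 8.86 to 0.00102 ± 0.00142 TPM. Another Gdh transcript (FBtr0089498), named here after its values were seen, rose by 1.18 on the log2 scale. CG4563 fell from 155 ± 3.52 to 3.71 ± 2.38 TPM and CG33109 from 31.5 ± 3.99 to 0.736 ± 0.784 TPM. A ferritin heavy chain transcript of Fer1HCH (FBtr0085633) fell 15.2-fold, from 157 ± 59.5 to 10.4 ± 2.02 TPM. Another Fer1HCH transcript (FBtr0085634) was also listed, and these values do not describe it. The mwh transcript fell from 27.8 ± 0.118 to 1.53 ± 0.826 TPM, and CG2772 and MFS1 fell 13.3- and 13.2-fold. The osi transcript fell from 16.5 ± 0.374 to 0.0305 ± 0.0431 TPM, and CG32795 from 10.2 ± 4.74 to 0.000112 ± 0.000158 TPM. CG32795 (X, 2782906 to 2789322) lies close to w (X, 2790599 to 2796466), the gene mutated in w1118. For CG32795 a difference in background at that locus and an effect of kdm5 cannot be told apart. Genes named in parentheses without a value in the paragraphs on gene lists were named after their values were seen. Listed transcripts of 20 genes, Gdh, Gclc and Gli among them, included both a higher and a lower one, and the division of reads between overlapping transcripts of 1 gene is uncertain.

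All 12 listed transcripts of antimicrobial peptide genes rose, out of 21 genes in the list. Besides DptA, DptB rose from 3.71 ± 1.9 to 244 ± 148 TPM, Mtk (Metchnikowin) rose 12.4-fold to 244 ± 113 TPM, and CecA1 (a cecropin) rose from 1.26 ± 0.0878 to 47.5 ± 33 TPM (SD, n = 2). The attacins AttA and AttC stood at 22.2 ± 12.3 and 49.5 ± 23.1 TPM in the mutant against 0.146 ± 0.00578 and 0.294 ± 0.00164 TPM in w1118. Each peptide transcript named here was higher in mutant replicate 2 than in mutant replicate 1, DptA at 699 against 247 TPM. The summed TPM of the 12 was 1453 ± 835 in the mutant and 61.8 ± 8.65 in w1118. These transcripts varied together between the mutant libraries, so the 12 are not independent results. The list stood higher than the other listed transcripts by camera with its preset correlation (adjusted p = 7.0e-06), and not with an estimated correlation (adjusted p = 0.66). In the same libraries the fat body marker Tsf1, the only listed gene of 14 in its list, rose 3.52-fold. A transcript of the haemocyte marker srp (FBtr0335424) rose from 2.36e-10 ± 3.34e-10 to 0.979 ± 0.0767 TPM. No other srp transcript was listed, so the level of that whole gene is unknown. The other listed haemocyte marker, Hml, stood lower, at 0.281 ± 0.159 against 0.757 ± 0.283 TPM (annotation-wide adjusted p = 1). Fat body and haemocytes also make antimicrobial peptides. In the IMD pathway, which controls many of these peptides, 6 of 9 listed transcripts were higher and 3 lower (camera adjusted p = 0.92). Of these, 3 rose (Rel, PGRP-SB1 and PGRP-LC) and 3 fell (pirk and both listed transcripts of PGRP-SC1b). As camera tests a shift of a list towards higher or towards lower, it cannot decide whether a list with members going both ways changed. Rel encodes the transcription factor of the pathway. Its listed transcript (FBtr0089340) was at 6.37 and 28.5 TPM in the mutant libraries and at 0 and 0.665 TPM in the w1118 libraries. No other Rel transcript was listed, so the level of the whole gene is unknown. PGRP-SB1 rose from 1.66 ± 1.32 to 35.2 ± 22.8 TPM. PGRP-SC1b, an amidase that breaks down peptidoglycan, fell 6.99-fold, from 3743 ± 118 to 535 ± 22.3 TPM. Of the Toll pathway genes and Bomanins, short secreted peptides induced through Toll, 10 of 10 listed transcripts were higher and 9 rose. BomBc1 rose from 0.7 ± 0.734 to 20.6 ± 4.49 TPM, BomS1 16.1-fold, BomS6 4.46-fold and BomBc2 4.31-fold. The camera adjusted p was 0.0015, and 0.29 with an estimated correlation. All 5 listed lysozyme transcripts fell: LysD from 32458 ± 1590 to 10601 ± 2416 TPM, LysB (FBtr0072628) 3.77-fold, LysE 3.6-fold and LysS 8.77-fold. In the JAK-STAT and Turandot list, 1 transcript was listed, that of Stat92E, at 1.8 ± 0.535 TPM in the mutant and 4.39 ± 1.41 TPM in w1118 (annotation-wide adjusted p = 0.61). Near-identical copies, such as the attacins AttA and AttB, the cecropins and the lysozymes LysB, LysD and LysE, share reads, so the level of a single member is uncertain.

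**Figure D2:**
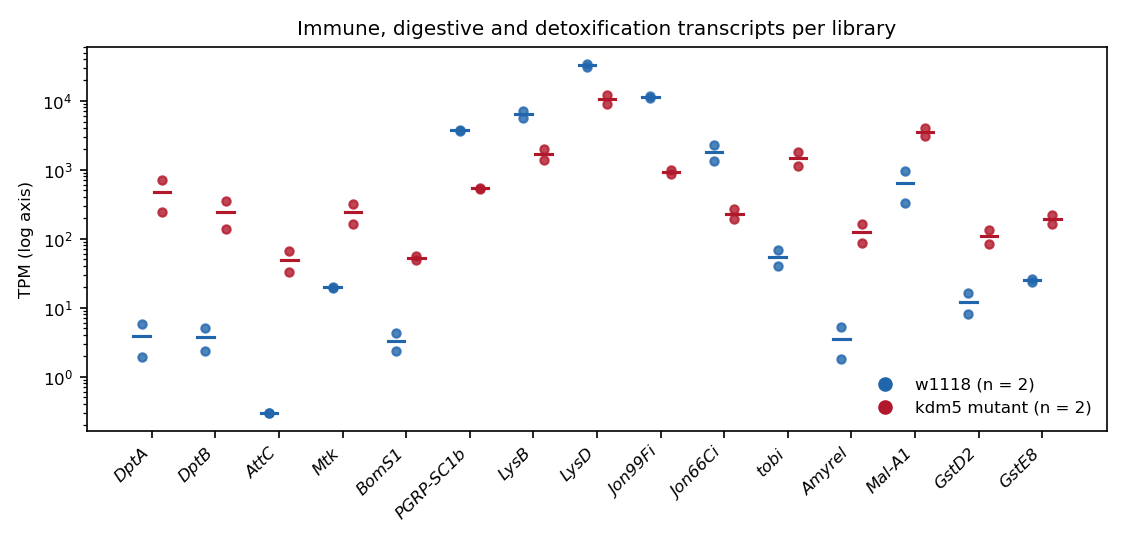
TPM of 15 transcripts on a log axis, 1 transcript per position, with blue points for the 2 w1118 libraries, red points for the 2 kdm5 mutant libraries, and a line at each group mean. Points of the 2 groups do not overlap for any transcript shown; DptA averages 473 TPM in the mutant and 3.89 TPM in w1118, and Jon99Fi 932 and 11260 TPM.

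Digestive serine proteases of the Jonah and trypsin families had 16 lower and 3 higher listed transcripts, of which 11 fell and 3 (Phae1, Ser6 and Try29F) rose. Jon66Cii fell from 380 ± 257 to 32.8 ± 5.6 TPM, Jon66Ci 7.85-fold and Jon99Fii 6.2-fold, from 10463 ± 383 to 1687 ± 120 TPM (SD, n = 2). Jon65Aiii, at 30065 ± 1587 TPM in w1118, fell 2.4-fold. Jon99Cii and yip7 stood at 25077 ± 179 and 17509 ± 1752 TPM in w1118 and at 11386 ± 905 and 9346 ± 202 TPM in the mutant (annotation-wide adjusted p = 0.062 and 0.22). The summed TPM of the listed members was 111839 ± 1119 in w1118 and 42589 ± 3127 in the mutant. The camera adjusted p was 2.4e-05, and 0.29 with an estimated correlation. Neighbouring Jonah genes such as Jon99Fi and Jon99Fii are near-identical and share reads.

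Carbohydrate-digesting enzymes had 8 higher and 3 lower listed transcripts, of which 7 rose and 1 (LManV) fell. The glucosidase tobi rose 26.7-fold, from 54.8 ± 20.7 to 1461 ± 484 TPM, the maltases Mal-A1 and Mal-A7 rose from 649 ± 447 to 3576 ± 698 TPM and from 165 ± 149 to 1708 ± 541 TPM, and the mannosidase LManIII rose 8.28-fold. As a list they did not pass camera (adjusted p = 0.064), but did without w1118 replicate 1 or 2 (adjusted p = 0.0041 and 0.00023); with an estimated correlation the adjusted p was 0.65. Lipid digestion, storage and synthesis had 16 lower and 3 higher listed transcripts, of which 5 fell (2 each of Acsl and Lsd-1, and Npc2c) and 2 rose. Transcripts of Acsl, an acyl-CoA synthetase, fell 3.28- and 2.62-fold (FBtr0333001 and FBtr0088701), while Lip3 and ATPCL, the ATP citrate lyase (3.1-fold), rose. The camera adjusted p for the lipid list, towards lower, was 0.0036, and 0.70 with an estimated correlation.

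Glutathione S-transferases and UDP-glycosyltransferases, enzymes that conjugate foreign and oxidised compounds, had 21 higher and 2 lower listed transcripts, of which 20 rose. GstD5 rose 14.8-fold, GstD2 from 12.2 ± 5.88 to 108 ± 35.5 TPM, GstD9 8.02-fold to 167 ± 49 TPM and GstE8 (FBtr0086676) 7.66-fold to 191 ± 39.5 TPM (SD, n = 2). The camera adjusted p was 0.00013, and 0.29 with an estimated correlation. Cytochrome P450 transcripts went both ways, with 11 higher and 7 lower, of which 7 rose and 2 (Cyp4d1 and Cyp4ac1) fell (camera adjusted p = 0.90). Cyp309a1 rose from 14.4 ± 10.5 to 102 ± 28.6 TPM and Cyp6a16 from 0.848 ± 0.488 to 5.59 ± 0.186 TPM, and Cyp4d1 fell 2.88-fold. Of 9 listed transcripts for reactive oxygen and oxidative stress, 7 were higher and 3 rose, among them Sod2, the mitochondrial superoxide dismutase, 4.35-fold (camera adjusted p = 0.46). Gclm rose 2-fold and Trx2 1.97-fold. In the same libraries 3 Malpighian tubule markers were higher: Oatp58Db rose 5.41-fold, ZnT35C rose 2.32-fold, and Oatp58Dc stood at 33 ± 2.98 against 15.3 ± 0.119 TPM. Malpighian tubules attach to the gut and express detoxification enzymes. Of 3 listed heat shock protein transcripts, Hsp67Bc rose from 1.23 ± 0.171 to 15.2 ± 11.5 TPM, Hsp60A rose 2.07-fold, and Hsc70-3 stood lower and was not called.

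Ribosomal protein transcripts were higher in 21 of 22 listed cases, of which 6 rose. RpLP1 (FBtr0331932) rose 10-fold, sta from 7.67 ± 0.967 to 28.8 ± 15.4 TPM and RpL36 2.18-fold, from 1071 ± 36.4 to 2334 ± 181 TPM. An RpS15Aa transcript stood at 16.3 ± 9.47 TPM in the mutant and 0.000547 ± 0.000774 TPM in w1118. The camera adjusted p was 0.011, and 0.85 with an estimated correlation. Oxidative phosphorylation had 3 higher and 4 lower listed transcripts (camera adjusted p = 0.92). The median log2 change of these 7 was -0.59 while their mean was 0.90 and camera pointed to higher. Those that rose were both listed transcripts of ND-15 (10.6- and 19.3-fold) and 1 of ND-B12 (4.22-fold), subunits of complex I. COX7A stood at 326 ± 4.94 TPM in the mutant and 555 ± 77.9 TPM in w1118 (annotation-wide adjusted p = 0.21).

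Barrier and cell type markers gave few transcripts that rose or fell. Of 6 listed septate junction and barrier transcripts, 5 were higher and none passed the annotation-wide test (limma; 3 passed over the listed transcripts, camera adjusted p = 0.76). Tsp2A, a tetraspanin of smooth septate junctions, stood at 28.2 ± 12.8 against 12.4 ± 3.95 TPM (SD, n = 2, mutant first). In the same order, crim stood at 11.5 ± 6.47 against 4.65 ± 0.693 TPM and a Gli transcript (FBtr0080768) at 11.5 ± 6.12 against 3.93 ± 0.224 TPM. The only lower transcript of the 6 was another Gli transcript (FBtr0343721), with a log2 change of -0.58, and it was not called. In the peritrophic matrix and mucin list, Crys rose 4.57-fold and obst-B rose, and Muc11A stood at 33.6 ± 17.8 against 84.6 ± 31.6 TPM. Enteroendocrine markers had 10 lower and 1 higher listed transcripts (camera adjusted p = 0.011, 0.051 without w1118 replicate 2, and 0.70 with an estimated correlation). None of the 10 passed the annotation-wide test: Tk (FBtr0335435) stood at 1.06 ± 0.431 against 2.81 ± 0.679 TPM, AstC at 3.54 ± 2.21 against 8.27 ± 1.66 TPM and Orcokinin at 68.8 ± 4.2 against 127 ± 4.06 TPM. The only listed Syt4 transcript (FBtr0081578) rose, from 0.00479 ± 0.00678 to 1.17 ± 0.412 TPM. The stem cell and enteroblast list had 2 lower transcripts, neither called; esg was at 0.676 ± 0.277 against 1.63 ± 0.552 TPM (limma adjusted p = 0.054 over the listed transcripts). The copper cell and proventriculus list also had 2 lower transcripts, neither called, with dve at 1.31 ± 0.454 against 2.92 ± 0.926 TPM. Of 3 enterocyte markers, Mal-A1 rose, nub stood at 1.65 ± 0.693 against 0.526 ± 0.0345 TPM and Myo31DF at 35.5 ± 6.37 against 55.2 ± 6.79 TPM.

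Few markers of other tissues were listed. Of 3 visceral muscle transcripts, Act57B stood at 116 ± 27.1 against 193 ± 57.3 TPM, TpnC73F at 25.7 ± 6.43 against 14.1 ± 2.6 TPM, and an Mhc transcript at 0.543 ± 0.395 TPM in the mutant against 5.07e-09 ± 7.16e-09 TPM in w1118. Tsf1 (transferrin), in the fat body list, rose 3.52-fold to 34 ± 6 TPM, and of the 2 haemocyte markers srp rose and Hml stood lower, as given above. Of 3 neuronal transcripts none was called, with Csp at 6.91 ± 2.35 against 13.2 ± 5.05 TPM and Syt1 at 1.7 ± 0.0928 against 0.829 ± 0.0236 TPM, and the photoreceptor gene ninaE stood at 0.426 ± 0.367 against 2.5 ± 1.77 TPM. Both cell cycle transcripts were higher: Bub3 rose 3.63-fold and aurB was at 4.84 ± 4.32 against 1.02 ± 3.54e-05 TPM. In amine synthesis and transport, Ddc (dopa decarboxylase) rose 4.97-fold and Hn stood at 4.7 ± 0.657 against 2.01 ± 0.489 TPM. No transcript was listed from the list of histone demethylases and KDM5 partners, which does not hold Kdm5 itself. Nor was any listed from histone genes, transposon and piRNA pathway genes, ovary and eggshell markers, or testis and male accessory gland markers. As the table lists only selected transcripts, this says nothing of their level.

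**Figure D3:**
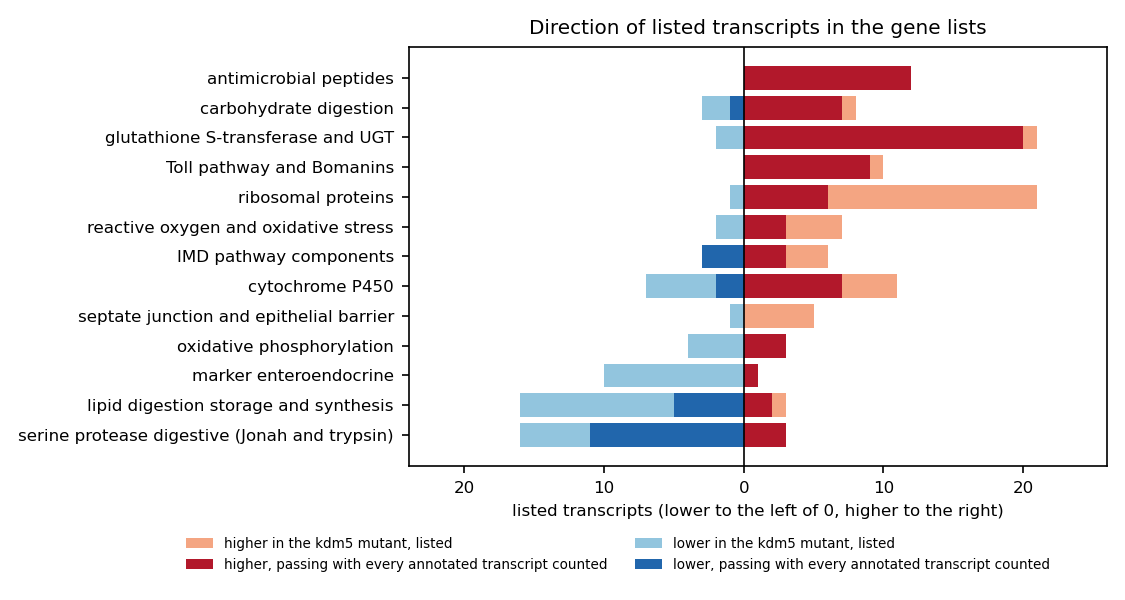
Number of listed transcripts in each of the 13 gene lists with at least 5 listed genes, higher in the kdm5 mutant to the right of 0 and lower to the left; pale bars count listed transcripts and dark bars in front of them count those passing limma with every annotated transcript counted as a test. All 12 antimicrobial peptide transcripts are dark on the right, and 11 of 16 lower Jonah and trypsin transcripts are dark on the left.

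Of the 13 gene lists tested, 7 passed camera at adjusted p < 0.05 with the preset correlation and 0 with an estimated correlation. By fry, which asks whether the members of a list move on balance one way, 8 lists passed, of which 4 were also called by camera: antimicrobial peptides (adjusted p = 0.040), glutathione S-transferases and UDP-glycosyltransferases (0.0053), the Toll list (0.0053) and the proteases (0.016). The other 4 were carbohydrate digestion, cytochrome P450 and oxidative phosphorylation (0.026 each) and reactive oxygen (0.047). Oxidative phosphorylation passed with 3 higher and 4 lower listed transcripts, the 3 higher being of ND-15 and ND-B12 alone. Lists called by camera that did not pass fry were lipids (0.33), ribosomal proteins (0.067) and enteroendocrine markers (0.099). Adjusted over the list alone, limma passed 12 of 12 antimicrobial peptide, 19 of 19 protease and 22 of 23 glutathione S-transferase and UDP-glycosyltransferase transcripts, counts that carry no weight because selection had nearly fixed them. All these tests ran on a list already selected for change. That matters most for fry, which compares members with no change rather than with the other listed transcripts, so passing was in part set beforehand.

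Called transcripts leaned to higher on each of the chromosome arms 2L, 2R, 3L, 3R and X, by 66.8% to 74.3%. Arm 2L, which carries Kdm5, had 175 higher and 74 lower calls (70.3% higher) against 69.4% on the other arms (odds ratio 1.04, two-sided Fisher's exact adjusted p = 0.82). No arm differed from the others, the smallest adjusted p being 0.58 for 2R and X.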

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

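The crossed block, the scaling, the annotation-wide adjustment, the counting of identical transcripts once and Fisher's test for lists were chosen after the data were examined; the others were planned. The count of 1358 called transcripts (946 higher, 412 lower) was 837 (600, 237) at adjusted p < 0.01 and 540 (387, 153) annotation-wide, both smaller by construction. An absolute log2 change of at least 1 left 248 lower transcripts. Leaving out 1 library, which leaves a lone sample assumed to vary like the others, gave 580 to 1239 calls (426 to 1014 higher, 154 to 287 lower) and annotation-wide 0 to 366, with 0 without either mutant library, where limma's prior carried few degrees of freedom. The annotation-wide count was 355 at adjusted p < 0.01. Whether equal replicate numbers mark a pair is not given in the labels. The correlation of same-numbered deviations was -0.19, but over transcripts selected on the comparison it cannot decide this. With the replicate block 933 transcripts were called, 269 of them lower. With the numbers crossed 1666 were called, 631 of them lower, and 1167 annotation-wide. The share of higher calls stayed above 50% under every setting run, from 62.1% to 73.8% with all 4 libraries. All settings used the same list, of which 58.8% was higher, so a share above 50% was in part set beforehand. No chromosome arm was called under any setting. Scaling to the TPM outside the listed transcripts moved the median log2 change by -0.13 and gave 1364 calls (62.4% higher), a shift too small to turn the direction of a listed change; 483 of the 540 annotation-wide calls were also called. The Kdm5 transcript kept its direction, with log2 changes of -2.78 with a pseudocount of 0.1 and -1.20 to -0.63 when 1 library was left out, short of the threshold at -0.94 and -0.89 without mutant replicates 1 and 2, and at -0.92 annotation-wide (adjusted p = 0.11). The 7 called lists became 0 with an estimated correlation. Fisher's test called 4 of them and not antimicrobial peptides (adjusted p = 0.059), Toll (0.070) or enteroendocrine markers (0.069). fry called 8, leaving out lipids, ribosomal proteins and enteroendocrine markers and adding carbohydrate digestion, P450, oxidative phosphorylation and reactive oxygen. Ribosomal proteins were lost at an absolute log2 change of at least 1 (0.11), where enteroendocrine markers were too few to test and 5 lists were called, and enteroendocrine markers without w1118 replicate 2 (0.051). Carbohydrate digestion was added with either block, without arm 2L, without values of 0 and without either w1118 library (0.00023 to 0.048). At adjusted p < 0.01, 5 lists were called. Lists that were not called turned direction: IMD to lower at mean TPM of at least 5 (adjusted p = 0.56), without values of 0 (0.80), at an absolute log2 change of at least 1 (0.34), without members of several lists or arm 2L (0.96 each) and without mutant replicate 1 (0.58 to 0.99 over the libraries left out); oxidative phosphorylation to lower at mean TPM of at least 5 (0.86) and without mutant replicate 1 or 2 (0.43 to 0.86 over the libraries left out); and P450 without mutant replicate 1 (0.60 to 0.99). The cause was not tested. No named transcript turned direction. DESeq2 size factors, DESeq2's test, count filters and the test planned for a table of comparisons alone were not run because the file holds TPM. Depth is unknown, so what it limits could not be given.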

Other observations

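Some gene families were picked by name after the values were seen, and all tests in this part were chosen only then. All 8 listed transcripts of V-ATPase subunits, parts of the proton pump that acidifies compartments, were lower in the mutant (median log2 change -0.73), but 6 were called over the listed transcripts and 0 annotation-wide. All 6 listed imaginal disc growth factor transcripts, which encode secreted chitinase-like proteins, were higher (log2 changes of 0.91 to 1.63); Idgf3 and Idgf4 passed annotation-wide. Subunits of the CCT chaperonin (6 of 6), the proteasome core (5 of 5), the nuclear pore (7 of 7) and the Mediator complex (6 of 6), and mitochondrial ribosomal proteins (8 of 9), were also higher, and annotation-wide 2, 4, 0, 0 and 1 of these passed. A binomial test of direction was adjusted over 22 groups, of which 19 were name prefixes with at least 5 listed genes. Of the prefixes, the Jonah proteases passed (0 higher, 12 lower, adjusted p = 0.00052), and CCT, Idgf, Nup and MED did not (adjusted p = 0.10 each). The other 3 groups, V-ATPase, proteasome and mitochondrial ribosomal proteins, were picked for their direction, so no test of it is given for them, and transcripts of 1 gene are not independent.

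The listed changes were uneven in size. Here rises and falls are listed transcripts higher or lower in the mutant, whether or not they passed a test. The smallest listed rise had a log2 TPM ratio of 0.82 and the smallest listed fall -0.58, a 1.49-fold change. The 50 rises nearest to no change had authors' p-values with a median of 0.0423, near the limit of the list, while the 50 nearest falls had a median of 0.0111 and reached 0.0042. Falls crowded at their limit, with 106 within 0.1 of it and 82 in the next 0.1, and then ended. A candidate explanation is a filter on the size of the falls besides the p, which no source used here describes. At equal ratios rises also had larger p than falls: between 0.8 and 1 on the log2 scale the medians were 0.0363 (139 rises) and 0.0058 (70 falls). That may come from composition, as the TPM outside the list was higher in the mutant by 0.15 on the log2 scale. The ratio at which the signed z of the authors' p crosses 0 was 0.18 in the first window of ratios and levels tried, but ranged from 0.03 to 0.18 over 18 windows, and the rises are truncated by the limit on p, so composition stays open.

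Listed transcripts lower in the mutant were longer than those higher in it, with median lengths of 2330 nt (717 transcripts) and 1449 nt (1024 transcripts) (permutation p = 2e-05, two-sided, the smallest the permutations can give; transcripts are not independent). Replicate libraries of 1 genotype also differed by length: mutant replicate 2 against 1 by 0.0927 and w1118 replicate 1 against 2 by 0.152 on the log2 scale per doubling of length. The slope between genotypes was -0.50, but it was measured on transcripts selected for that contrast, so a length-dependent difference between libraries, such as in RNA breakdown or fragment selection, and a difference between genotypes cannot be told apart here.

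The genotypes may also differ in background, near the mutated locus on arm 2L or elsewhere. Of the 60 transcripts with an absolute log2 change of at least 3, 15% lay on 2L, against 18.2% of the other listed transcripts (odds ratio 0.793, 95% Woolf interval 0.386 to 1.63, two-sided Fisher's exact p = 0.61). The interval is too wide to exclude an excess, and differences elsewhere in the genome were not tested. On the X chromosome, w rose and CG32795 close to it fell, and w1118 carries a mutated w. The kdm5 genotype, the biological difference the design names, stays open as an untested explanation of the difference in length and of the large changes.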
